A study of Mus musculus with 12 samples.

How the data were processed

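Transcript levels were measured in neutrophils from mouse bone marrow, 3 biological replicates each of resting C57Bl/6J, IC C57Bl/6J, resting MRL/MpJ and IC MRL/MpJ cells, 12 arrays in all. Per the labels, total RNA was extracted with TRIzol, treated with DNase and labelled with biotin for Affymetrix arrays. The treatment protocol speaks of both IC and phorbol myristate acetate, while each sample is labelled either as unactivated or as activated with IC; the groups here follow the sample labels, and whether any sample also met the phorbol ester is not given in the sources used here. The time of stimulation, the number and sex of the animals, and whether cells were pooled are not given in the sources used here.

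The authors named oligo and RMA as their processing tools, and the deposited values are log2 expression per probe set, with 2 decimals and 1 column per array. The versions, the annotation package and the level at which probe sets were summarised are not given in the sources used here. The log2 unit was read from the values, which ran from 3.21 to 14.25 over the 12 arrays. RMA values are relative to the other arrays of the series, and the table carries no detection calls. Medians over all probe sets ran from 6.72 to 7.04, and the highest Pearson r of an array with another was 0.996. Raw intensities were not analysed here.

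Of 34390 probe sets, 23521 carried 1 gene symbol, 1814 several and 9055 no gene in the annotation table used here. Only probe sets with 1 symbol were named and tested. Of several probe sets of a gene (1082 genes), the one with the highest mean over the 12 arrays was kept, which gave 22180 genes, 21994 of them with a gene ID in the RefSeq table of the mouse assembly GRCm38.p6. That table served only to find neighbouring genes. List members without a probe set of their own were not analysed here.

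The comparisons, their tests, 26 gene lists and the rule for named genes were fixed before the data were examined. limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 12 arrays, so that the groups shared 1 estimate of spread, with no replicate block. Moderated two-sided tests (eBayes) were adjusted by the Benjamini-Hochberg method over all genes within a comparison, with an adjusted p under 0.05 as the threshold, and no gene was filtered out. There were 6 contrasts: IC against resting in each strain, MRL/MpJ against C57Bl/6J in each state, the difference of the 2 responses (the interaction) and their mean. Changes are log2 differences with the SE of the model. The median SE was 0.113 for a difference of 2 groups, 0.159 for the interaction and 0.080 for the mean response. With 3 arrays against 3 the smallest two-sided exact p is 0.1, so that calls rest on the spread limma shares between genes (prior degrees of freedom 5.27). As a description, correlations across genes and overlaps of calls compared the responses of the strains and the strain differences of the states.

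The lists covered NF-kB target cytokines, NF-kB feedback genes, immediate early genes, interferon-stimulated genes, Fc receptors with proximal kinases, chemoattractant and growth factor receptors, oxidase subunits, 2 granule classes, adhesion, proliferation, glycolysis, cholesterol, heat shock, oxidative stress, inflammasome, leukotriene and MHC genes. Markers of monocytes, B cells, T and NK cells, erythroid cells, eosinophils with basophils and mast cells, megakaryocytes and dendritic cells, and ribosomal protein genes, completed them. Each was tested with camera at a preset correlation between genes of 0.01, adjusted over the 26 lists, and beside it with camera at an estimated correlation and with fry, which tests against no change rather than against other genes. Members were counted when adjusted over all genes and when adjusted over the list alone. The rule for named genes took, per comparison, the 6 largest rises and the 6 largest falls among called genes whose groups did not overlap (no such condition for the interaction and the mean). Names such as Gm with digits or Rik, predicted genes, small RNAs and single immunoglobulin or T cell receptor segments were left out. From each list it took up to 3 called members with the largest change, or else the member with the smallest p, and Nnt served as a strain check. Not every gene that this rule selects is reported here. Genes outside this rule are marked as chosen after their values were seen.

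The steps were tested on simulated data in 1 comparison of 22180 genes. A true log2 change of 0.5, 1 and 2 was called in 55.2%, 95.5% and 98.5% of changed genes, with 8 false calls among unchanged genes. Noise was drawn independently for each gene and array, so that genes varying together and paired arrays were not simulated. Resting and IC arrays of the same number share only a number in the labels. Their deviations from the group means were correlated at 0.35, 0.27 and 0.12 in C57Bl/6J, each over the 0.1 set as the bound, so that in this strain the numbers were taken, from the data alone, to pair the samples. Alternatives were quantile, cyclic loess and 75th percentile scaling, leaving out the dimmest 33.3% or 50% of genes, the mean of a gene's probe sets, all probe sets, an intensity trend with robust variance, array quality weights, replicate blocks, only the groups compared, stricter thresholds and leaving out each array. Figures were drawn with matplotlib 3.10.9 and tables joined with pandas 2.3.3 in Python 3.11.15.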

Results

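Neutrophils were taken from the bone marrow of mice of 2 strains, MRL/MpJ and C57Bl/6J, and were either left unactivated (resting) or activated with immune complexes (IC), complexes of antigen and antibody that engage Fc receptors. The series concerns skin inflammation in a mouse model of epidermolysis bullosa acquisita, a blistering disease driven by autoantibodies. Its stated purpose was to find the molecular basis of the different response of the strains to IC. RNA of 12 samples was hybridised to Affymetrix arrays, 3 biological replicates in each of 4 groups, and 22180 genes were tested. The number of arrays limits the precision: the median standard error (SE) of a log2 difference between 2 groups was 0.11. Values below are log2 expression after robust multi-array averaging (RMA), group means carry the SD over n = 3 arrays, and differences carry the SE of the limma model.

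The strains were separated by the first principal component of the arrays (35.3% of the variance) and the states by the next (20.2%). Nnt, the mitochondrial transhydrogenase gene in which C57Bl/6J mice carry a known deletion, was lower in all 6 C57Bl/6J arrays than in all 6 MRL/MpJ arrays. Its level was 9.14 ± 0.11 in resting C57Bl/6J and 10.10 ± 0.03 in resting MRL/MpJ neutrophils, a difference of 0.97 ± 0.09 (limma, adjusted p = 1.58e-05). Which exons the Nnt probes cover was not analysed here. The array of C57Bl/6J IC replicate 2 stood apart from the rest, with a median over all probe sets of 7.04 against 6.72 to 6.90 in the other 11 arrays.

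The first comparison asked how IC changed transcripts in C57Bl/6J neutrophils. Arrays labelled IC had far lower levels of immediate early genes, the transcription factors and signalling regulators that cells switch on within minutes of a stimulus. Egr1, a zinc finger factor of this class, fell by 2.99 ± 0.18 on the log2 scale, from 12.77 ± 0.12 to 9.77 ± 0.35 (limma, adjusted p = 2.58e-06). The G protein regulator Rgs1 fell by 2.11 ± 0.16, and the small Maf factor Mafk by 1.70 ± 0.11. The prostaglandin E2 receptor Ptger2 (1.34 ± 0.13) and the C5a receptor C5ar2 (1.09 ± 0.10) were higher. These directions follow the labels as given.

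In all, 736 genes passed the threshold, 565 higher and 171 lower with IC, and 67 of them changed at least 2-fold (28 higher, 39 lower). The largest rises were those of the acute phase gene Saa3 (2.10 ± 0.31; limma, adjusted p = 0.00181) and of Pilrb1, an activating paired immunoglobulin-like receptor (2.10 ± 0.17; adjusted p = 2.80e-05). Oscp1, Card6, Pilrb2 and the interferon lambda receptor chain Ifnlr1 rose by 1.83, 1.58, 1.57 and 1.37. Besides Egr1, Rgs1 and Mafk, the largest falls included those of the circadian repressor Ciart (-2.08 ± 0.22) and the monocyte chemoattractant Ccl2 (-1.88 ± 0.20). Of these genes only Pilrb2 lost its call in an alternative at the same threshold, with only the groups compared in the model (limma, adjusted p = 0.0559).

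Of 32 immediate early genes measured, 23 fell, 1 rose and 8 were not called (24 fell and 1 rose adjusted over the list alone). Their median change was -0.72 (camera, adjusted p = 4.18e-37), and the mean of the list was 11.39 ± 0.11 in resting and 10.64 ± 0.21 in IC arrays. Of 25 cytokines and chemokines that are NF-kB targets, 7 fell, 2 rose and 16 were not called (10 fell and 3 rose adjusted over the list alone; camera, adjusted p = 9.12e-05). The oncostatin gene Osm (-1.35) and the neutrophil chemoattractant Cxcl2 (-1.17) fell, the call of Cxcl2 being lost without both C57Bl/6J arrays numbered 2 (limma, adjusted p = 0.0832). The call of this list was lost with an estimated correlation (adjusted p = 0.350) and without C57Bl/6J IC replicate 2 (adjusted p = 0.0534). Among 25 genes of NF-kB feedback and survival, 5 rose, including Tnfaip2 (1.09) and Tnip1 (0.57), and 20 were not called (11 rose and 2 fell adjusted over the list alone). That list was called higher (camera, adjusted p = 0.000566), with adjusted p = 0.306 with an estimated correlation and 0.138 without C57Bl/6J IC replicate 1.

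Fc receptors and the kinases and phosphatases next to them were higher as a list: 3 of 23 rose and 20 were not called (8 rose adjusted over the list alone). The activating IgG receptors Fcgr4 and Fcgr3 rose by 0.79 ± 0.11 and 0.55 ± 0.09, and Ptpn6, the phosphatase SHP-1, by 0.68 ± 0.09. With only the groups compared in the model, Fcgr3 and the C5a receptor C5ar1 were not called (limma, adjusted p = 0.0539 and 0.0968). The call of the list was made with the preset correlation (camera, adjusted p = 1.65e-05) and with an estimated correlation (adjusted p = 0.0214). Of 24 receptors for chemoattractants and growth factors, 4 rose, among them C5ar2 and C5ar1 (0.64), and 2 fell, among them Ccr1 (-0.97), while 18 were not called (7 rose and 2 fell adjusted over the list alone). The list was called higher (camera, adjusted p = 0.00925), but not with an estimated correlation (adjusted p = 0.350), nor without C57Bl/6J resting replicate 1 (adjusted p = 0.0853) or IC replicate 3 (adjusted p = 0.0742).

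Genes of cholesterol synthesis and uptake were lower. Of 14 measured, 4 fell, including Hmgcs1 (-1.57 ± 0.22), Insig1 (-1.05 ± 0.11) and Sc5d (-0.96 ± 0.10), and 10 were not called (7 fell adjusted over the list alone; camera, adjusted p = 3.63e-08; adjusted p = 0.175 with an estimated correlation). Of 22 heat shock and unfolded protein response genes, 3 fell (3 also adjusted over the list alone) and 19 were not called, with Ddit3, the stress factor CHOP, at -1.70 ± 0.15. The list was called lower (camera, adjusted p = 9.96e-05), but not with an estimated correlation (adjusted p = 0.376) or without C57Bl/6J IC replicate 2 (adjusted p = 0.0614). Of 29 proliferation genes, 3 fell and 26 were not called (8 fell adjusted over the list alone; camera, adjusted p = 7.01e-06; adjusted p = 0.350 with an estimated correlation). Of 18 markers of eosinophils, basophils and mast cells, 1 rose and 17 were not called (2 rose adjusted over the list alone; median 0.29; camera, adjusted p = 0.00206; adjusted p = 0.306 with an estimated correlation).

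The other 17 lists were not called in C57Bl/6J. Among granule and oxidase genes, the NADPH oxidase subunits and the azurophil granule list had an adjusted p of 0.291 each, and the specific and gelatinase granule list 0.785 (camera). Adhesion and surface activation genes held 2 that rose, Clec4n (1.28) and Olr1 (0.58), and 2 that fell, of 21 (5 rose and 2 fell adjusted over the list alone; camera, adjusted p = 0.291). Of 16 leukotriene and prostaglandin genes, Ptger2 and the prostacyclin receptor Ptgir (1.05 ± 0.14) rose and the cyclooxygenase Ptgs2 fell by 1.04 ± 0.21 (2 rose and 2 fell adjusted over the list alone; camera, adjusted p = 0.189). The call of Ptgs2 was lost without resting replicate 2 (limma, adjusted p = 0.0832) or IC replicate 3 (limma, adjusted p = 0.0553), and without both C57Bl/6J arrays numbered 2 (limma, adjusted p = 0.154). Of 22 inflammasome and cell death genes, 3 rose, including the death receptor Fas (0.95) and Nlrp12 (0.61), and 19 were not called (6 rose and 1 fell adjusted over the list alone; camera, adjusted p = 0.247). Glycolysis and hypoxia genes had an adjusted p of 0.308 (camera). The oxidative stress list had a median of 0.03 but a mean of -0.12 and was not called (camera, adjusted p = 0.185). None of 26 interferon-stimulated genes (camera, adjusted p = 0.291) and none of 18 genes of MHC class I and II (camera, adjusted p = 0.367) was called.

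Markers of other cell types did not follow the immediate early genes. The adjusted p was 0.991 for monocyte and macrophage markers and for B cell markers, and 0.785 for T and NK cell markers, of which 1 rose and 2 fell of 19 (2 rose and 2 fell adjusted over the list alone), among them perforin (Prf1, -0.67). It was 0.838 for erythroid, dendritic cell and ribosomal protein genes, and 0.564 for megakaryocyte and platelet markers (camera). In the glycolysis, monocyte, T and NK cell and erythroid lists the median lay above 0 while the camera direction was down. The share of called genes that were higher was 76.8% in the deposited values and 66.3%, 60.3% and 62.3% after quantile, cyclic loess and 75th percentile scaling. The count fell to 382 without resting replicate 2, to 380 without resting replicate 3, to 397 without both C57Bl/6J arrays numbered 2, and to 246 when only the groups compared entered the model, and it was 1825 with array quality weights.

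The same question was asked in MRL/MpJ neutrophils. Arrays labelled IC again had lower immediate early genes, and the chemokine genes named below were lower too. Egr1 fell by 3.79 ± 0.18, from 12.56 ± 0.03 to 8.77 ± 0.36 (limma, adjusted p = 2.47e-07), Rgs1 by 2.72 ± 0.16, and Egr3 by 2.06 ± 0.11. The chemokine genes Ccl2 and Cxcl2 fell by 2.34 ± 0.20 and 2.07 ± 0.21, and Ptgs2 by 2.19 ± 0.21 (limma, adjusted p = 3.72e-05). C5ar2 rose by 1.24 ± 0.10 and Ptger2 by 1.33 ± 0.13.

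Of the 22180 genes, 1109 passed, 674 higher and 435 lower, and 119 changed at least 2-fold (44 higher, 75 lower). The largest rises were those of the myeloid receptor Treml4 (1.67 ± 0.23; limma, adjusted p = 0.000629), Card6 (1.58), the adaptor Sh3bp2 (1.53), Saa3 (1.51), the apelin receptor Aplnr (1.46) and Ifnlr1 (1.46). The largest falls beside those named were the lipid droplet gene Hilpda (-2.50 ± 0.17; limma, adjusted p = 3.55e-06) and Ciart (-2.34 ± 0.22). The call of Saa3 was lost without resting replicate 1 (limma, adjusted p = 0.0627) or IC replicate 2 (limma, adjusted p = 0.0549).

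Of the 32 immediate early genes, 24 fell, 1 rose and 7 were not called (28 fell and 1 rose adjusted over the list alone), with a median of -1.07 (camera, adjusted p = 4.47e-44). The mean of the list went from 11.29 ± 0.03 to 10.18 ± 0.11. Of the 25 NF-kB target cytokines and chemokines, 11 fell, led by Ccl2, Ptgs2 and Cxcl2, 1 rose and 13 were not called (13 fell and 1 rose adjusted over the list alone). Camera called the list lower (adjusted p = 4.51e-13), but not with an estimated correlation (adjusted p = 0.0987). The NF-kB feedback and survival genes went both ways, with 4 that rose, 5 that fell and 16 not called (5 rose and 7 fell adjusted over the list alone; camera, adjusted p = 0.161). Tnfaip2 rose by 0.92 and the maturation marker Cd83 fell by 1.08.

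Of 23 Fc receptor and proximal kinase genes, 8 rose and 15 were not called (12 rose and 1 fell adjusted over the list alone), including Ptpn6 (0.80 ± 0.09) and the kinase subunit Pik3cg (0.55 ± 0.10). The list was called higher with the preset correlation (camera, adjusted p = 1.65e-09) and with an estimated correlation (adjusted p = 0.00283). Fcgr4 rose by 0.57 ± 0.11, a call lost without resting replicate 2 (limma, adjusted p = 0.0595). Chemoattractant and growth factor receptors went both ways, 6 up and 4 down of 24 (9 rose and 7 fell adjusted over the list alone; camera, adjusted p = 0.359), with C5ar2 higher and the chemokine receptor Ccr1 (-1.18) lower.

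Cholesterol synthesis and uptake genes fell in 7 of 14 cases (7 fell and 1 rose adjusted over the list alone), with Hmgcs1 at -1.78 ± 0.22, Insig1 at -1.25 ± 0.11 and Cyp51 at -1.23 ± 0.22. Camera called the list lower (adjusted p = 1.65e-09), with adjusted p = 0.0987 with an estimated correlation. Proliferation genes (6 of 29 fell, 7 adjusted over the list alone; camera, adjusted p = 5.45e-07) and heat shock and unfolded protein response genes (4 of 22 fell, 6 adjusted over the list alone; camera, adjusted p = 1.15e-05) were lower, with adjusted p of 0.335 and 0.365 with an estimated correlation. The mitotic kinase Aurka was at -0.66 and Ddit3 at -1.64. The specific and gelatinase granule list was called higher (2 of 26 rose, 2 adjusted over the list alone; camera, adjusted p = 0.0422), with adjusted p = 0.667 with an estimated correlation. That call was lost without IC replicate 2 (adjusted p = 0.117), resting replicate 2 (adjusted p = 0.138) or IC replicate 3 (adjusted p = 0.0892). The other 19 lists were not called, among them B cell markers, of which Cd79b rose by 0.80 ± 0.14, and interferon-stimulated genes, with 1 that rose, 2 that fell and 23 not called (3 rose and 3 fell adjusted over the list alone). The count of called genes fell to 616 without IC replicate 1 and to 665, 576 and 719 without resting replicates 1, 2 and 3, and was 5529 with array quality weights.

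**Figure D1:**
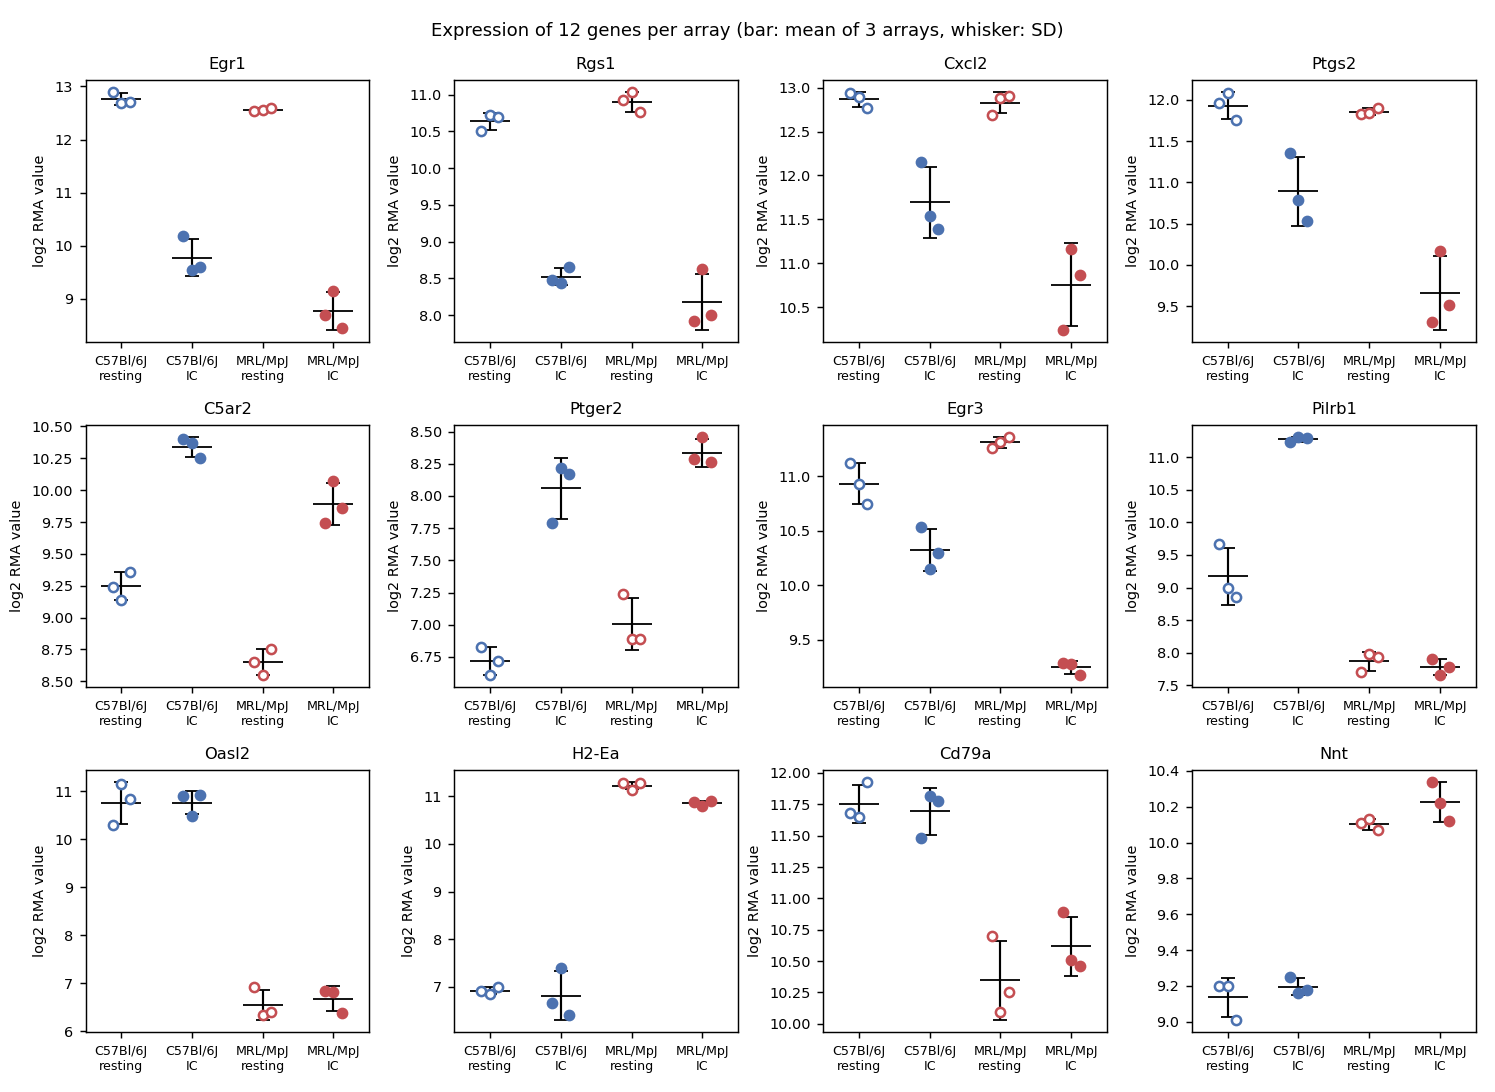
Log2 RMA expression of 12 genes in each array, by strain and state, with open circles for resting and filled circles for IC arrays, blue for C57Bl/6J and red for MRL/MpJ, the mean of 3 arrays as a bar and the SD as whiskers. Egr1 lies near 12.77 and 12.56 in the resting groups and near 9.77 and 8.77 in the IC groups. Pilrb1 is highest in the C57Bl/6J IC arrays, at 11.27, and lies higher in resting C57Bl/6J than in either MRL/MpJ group.

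Averaged over both strains, 2003 genes differed between IC and resting arrays, 1402 higher and 601 lower, and 82 changed at least 2-fold (30 higher, 52 lower). Egr1 fell by 3.39 ± 0.13, Rgs1 by 2.42 ± 0.11 and Ciart by 2.21 ± 0.16, and Saa3 (1.81 ± 0.22), Card6 (1.58 ± 0.12) and Ifnlr1 (1.41 ± 0.08; limma, adjusted p = 3.74e-07) rose. Of the immediate early genes, 26 of 32 fell and 1 rose (28 fell and 2 rose adjusted over the list alone; camera, adjusted p = 4.57e-42; adjusted p = 0.0248 with an estimated correlation). Of the Fc receptor and proximal kinase genes, 12 of 23 rose, among them Ptpn6 (0.74), Fcgr4 (0.68) and Pik3cg (0.46), and none fell (14 rose and 1 fell adjusted over the list alone; camera, adjusted p = 8.50e-09; adjusted p = 0.00396 with an estimated correlation). NF-kB target cytokines (11 of 25 fell and 1 rose; 12 fell and 2 rose adjusted over the list alone), cholesterol (7 of 14 fell and 1 rose; 8 fell and 1 rose adjusted over the list alone), proliferation (9 of 29 fell, 10 adjusted over the list alone) and heat shock genes (5 of 22 fell, 5 adjusted over the list alone) were called lower. With an estimated correlation their adjusted p was 0.191, 0.127, 0.263 and 0.327 (camera). Markers of eosinophils, basophils and mast cells were called higher (2 of 18 rose, 2 adjusted over the list alone; median 0.19; camera, adjusted p = 0.00264; adjusted p = 0.263 with an estimated correlation). The share of called genes that were higher was 70.0% and became 59.6% after cyclic loess scaling, and the count of called genes was 5291 with array quality weights.

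The responses of the strains were then set side by side. Across the 22180 genes the log2 changes had a Pearson r of 0.642 and a Spearman correlation of 0.446. These are correlations across genes, which are not independent replicates, between sets of arrays with none in common. Of the genes called, 346 rose and 141 fell in both strains, against 17.2 and 3.35 for independent lists of those sizes, and 0 were called in opposite directions. Of 1358 genes called in either strain, 95.1% changed with the same sign.

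**Figure D2:**
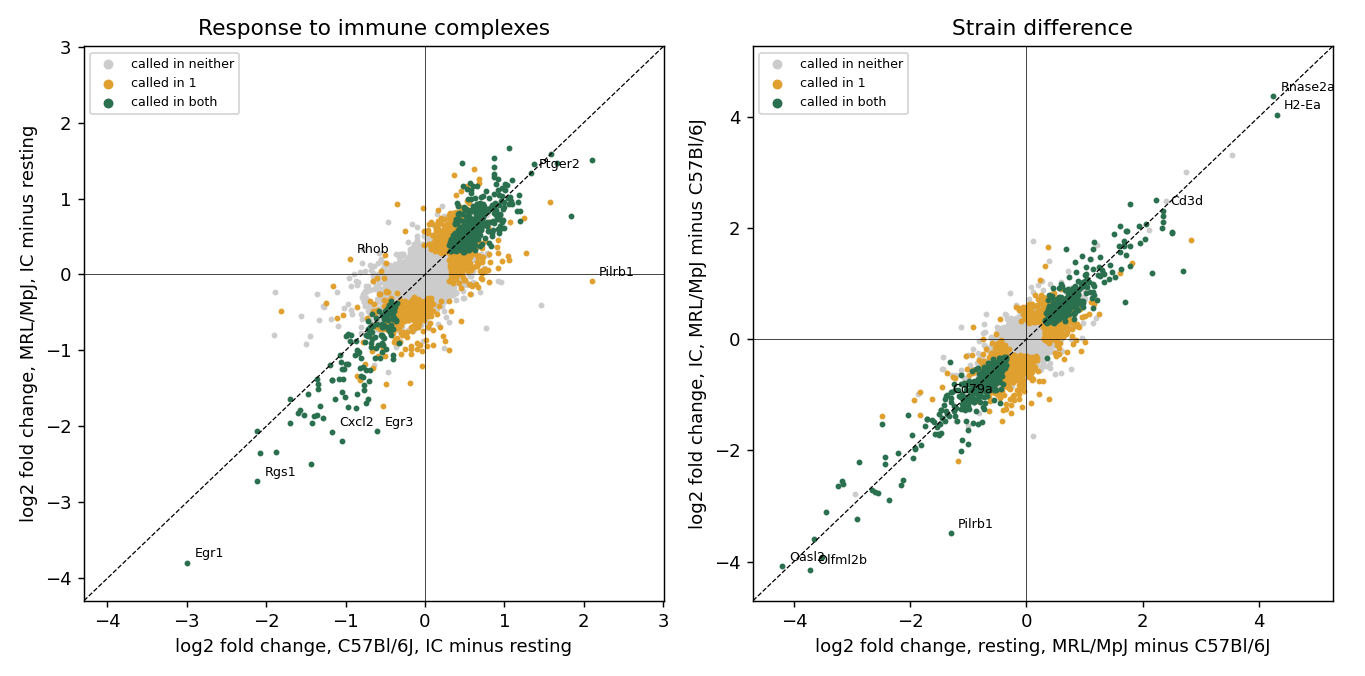
Log2 fold changes of 22180 genes, each point a gene, without error bars. The left panel sets the IC response in MRL/MpJ against that in C57Bl/6J (r = 0.642) and the right panel sets the strain difference in IC arrays against that in resting arrays (r = 0.758), with the dashed line marking equal change and colours marking genes called in neither, 1 or both comparisons.

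The next comparison set the strains against each other at rest. Resting MRL/MpJ neutrophils had much lower interferon-stimulated genes than resting C57Bl/6J neutrophils. Oasl2, an oligoadenylate synthetase-like antiviral gene, was at 6.56 ± 0.32 in MRL/MpJ and 10.76 ± 0.44 in C57Bl/6J, a difference of -4.20 ± 0.22 (limma, adjusted p = 1.30e-07). The B cell receptor chain Cd79a (-1.41 ± 0.16) and the B cell gene Cd22 (-1.48 ± 0.13) were lower too. The MHC class II chain H2-Ea, which C57Bl/6J mice are known not to express, was higher in MRL/MpJ (11.22 ± 0.08 against 6.92 ± 0.08; limma, adjusted p = 1.06e-08). Its level in C57Bl/6J lay near the median over all probe sets, so that the fitted difference of 4.30 ± 0.18 rests on the background of the array. The same holds for Oasl2 in MRL/MpJ, at 6.56. Other large strain differences may also have a low side near background, which was not judged gene by gene.

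Of 1007 genes called, 600 were higher and 407 lower in MRL/MpJ, and 171 differed at least 2-fold (72 higher, 99 lower). The share that was higher, 59.6%, became 48.6% after cyclic loess scaling. Beside H2-Ea, the largest differences upward were those of the ribonuclease Rnase2a (4.25 ± 0.17; limma, adjusted p = 9.60e-09), the histidine ammonia lyase Hal (2.70), the interferon-inducible Ifi202b (2.50), the T cell receptor subunit Cd3d (2.35) and Emp1 (2.34). After Oasl2, the largest downward were those of Olfml2b (-3.72 ± 0.15; limma, adjusted p = 9.60e-09), Oas1g (-3.65), the tripartite motif genes Trim12a (-3.52) and Trim30d (-3.45), and Ifi204 (-3.24).

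Of 26 interferon-stimulated genes, 16 were lower and 10 were not called (16 lower and 1 higher adjusted over the list alone), with a median of -0.68 (camera, adjusted p = 1.21e-23; adjusted p = 0.0350 with an estimated correlation). The oligoadenylate synthetase Oas2 (-2.21 ± 0.13) and Usp18 (-1.96 ± 0.21), which removes ISG15 from proteins, were among them. The mean of the list was 8.12 ± 0.08 in MRL/MpJ and 8.98 ± 0.11 in C57Bl/6J. Of 17 B cell markers, 10 were lower, including Cd22, Cd79a and Ms4a1 (-1.41 ± 0.14), 1 was higher and 6 were not called (11 lower and 1 higher adjusted over the list alone). Their median was -0.98 (camera, adjusted p = 2.65e-15; adjusted p = 0.142 with an estimated correlation). Of 18 MHC class I and II genes, 8 were lower, among them the class II chains H2-Ab1 (-0.93 ± 0.14) and H2-Aa (-0.81 ± 0.12), 1 was higher, H2-Ea, and 9 were not called (12 lower and 2 higher adjusted over the list alone). B cells also express class II genes, and the markers of B cells moved the same way. The class I gene H2-K1 was lower too, and the cause of the lower MHC genes was not tested. Camera called the MHC list lower (adjusted p = 1.81e-07), but not with an estimated correlation (adjusted p = 0.283).

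Markers of eosinophils, basophils and mast cells were called higher in MRL/MpJ (2 of 18 higher, 16 not called; 7 higher and 1 lower adjusted over the list alone; median 0.39; camera, adjusted p = 0.000268; adjusted p = 0.256 with an estimated correlation). The eosinophil granule gene Prg2 was at 0.76 ± 0.16 (limma, adjusted p = 0.0150, and 0.0506 to 0.0650 in 5 of the 6 fits that left out 1 array). Azurophil granule and promyelocyte genes were called higher as a list (1 higher, 1 lower and 12 not called of 14; 7 higher and 1 lower adjusted over the list alone; median 0.23; camera, adjusted p = 0.00190; adjusted p = 0.518 with an estimated correlation). The remaining 21 lists were not called. Within the specific and gelatinase granule list, 5 genes were lower, led by the integrin Itgb2l (-1.72 ± 0.10), and 2 higher, led by Stfa3 (1.53 ± 0.23), with 19 not called (6 lower and 3 higher adjusted over the list alone). Among Fc receptor genes, Fcgr4 was lower (-0.91 ± 0.11; limma, adjusted p = 0.000294) and 1 more of 23 was lower (2 lower adjusted over the list alone; camera, adjusted p = 0.545). The chemoattractant receptor list held C5ar2 (-0.60 ± 0.10) and P2ry2 (0.73 ± 0.12). The cholesterol regulator Stard4 (1.21) and the adhesion gene Vcam1 (1.17) were higher. Immediate early genes (1 higher, 2 lower of 32; 2 higher and 3 lower adjusted over the list alone; camera, adjusted p = 0.0983) and NF-kB target cytokines (1 higher of 25, 1 adjusted over the list alone; camera, adjusted p = 0.964) were not called at rest. The ribosomal gene Rpl3 was at 1.47 in the brightest of its probe sets and at -0.34 and -0.09 in the others, and the mean of its probe sets was not called (limma, adjusted p = 0.191). The count fell to 541 without C57Bl/6J resting replicate 2 or 3, and to 594, 554 and 623 without MRL/MpJ resting replicates 1, 2 and 3, and was 1670 when only the groups compared entered the model and 3020 with array quality weights.

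Between the strains in arrays labelled IC, the interferon-stimulated genes and B cell markers were lower in MRL/MpJ as at rest, and immediate early and NF-kB target genes were lower as well, but none of these 4 list calls held with an estimated correlation (camera, adjusted p = 0.0638, 0.267, 0.272 and 0.272). Oasl2 was at -4.09 ± 0.22, and Rnase2a (4.37 ± 0.17) and H2-Ea (4.04 ± 0.18) were higher. As at rest, differences of this size may rest on the background of the array. Egr3 (-1.08 ± 0.11), Nr4a1 (-1.07 ± 0.12) and Ptgs2 (-1.23 ± 0.21; limma, adjusted p = 0.00366) were lower. The receptor Pilrb1 was at 7.78 ± 0.12 in MRL/MpJ and 11.27 ± 0.04 in C57Bl/6J IC arrays, a difference of -3.49 ± 0.17 (limma, adjusted p = 4.45e-08).

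Of 1123 genes called, 468 were higher and 655 lower in MRL/MpJ, and 185 differed at least 2-fold (62 higher, 123 lower). The largest differences also included cathepsin E (Ctse, 2.50 ± 0.08; limma, adjusted p = 2.06e-09), Cd3d (2.31), Emp1 (2.21) and Fah (2.07) upward, and Olfml2b (-4.15), Trim12a (-3.91), Oas1g (-3.59) and Trim30d (-3.12) downward. The share that was higher, 41.7%, became 52.7% after 75th percentile scaling.

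Of the interferon-stimulated genes, 16 of 26 were lower and 10 were not called (17 lower adjusted over the list alone; camera, adjusted p = 2.13e-19; adjusted p = 0.0638 with an estimated correlation), including Oas2 (-2.05) and Oas3 (-1.90). Of the B cell markers, 10 of 17 were lower and 1 higher (13 lower and 1 higher adjusted over the list alone; camera, adjusted p = 6.01e-12; adjusted p = 0.267 with an estimated correlation), with Cd22 at -1.28 and Fcrla at -1.47. Of the MHC genes, 10 of 18 were lower and 1 higher (13 lower and 2 higher adjusted over the list alone; camera, adjusted p = 2.50e-06; adjusted p = 0.272 with an estimated correlation). Immediate early genes were lower in 12 of 32 cases and 20 were not called (19 lower adjusted over the list alone; camera, adjusted p = 1.59e-12), with the kinase gene Plk2 at -1.89. NF-kB target cytokines were lower in 8 of 25 cases, 1 was higher and 16 were not called (13 lower and 1 higher adjusted over the list alone; camera, adjusted p = 1.33e-06). NF-kB feedback genes were lower in 5 of 25 cases, among them the inhibitor Nfkbie (-0.65), with 20 not called (9 lower adjusted over the list alone; camera, adjusted p = 0.00146). With an estimated correlation these 3 lists had an adjusted p of 0.272 each, and the feedback list was not called without C57Bl/6J IC replicate 1 (adjusted p = 0.179).

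Camera called 4 more lists. Receptors for chemoattractants and growth factors were lower in 5 of 24 cases and higher in 2 (8 lower and 2 higher adjusted over the list alone; adjusted p = 0.0292; adjusted p = 0.456 with an estimated correlation), with the lipopolysaccharide co-receptor Cd14 at -1.03 ± 0.12 and the tumour necrosis factor receptor Tnfrsf1b at -0.81 ± 0.09. Heat shock genes were called lower (1 of 22 lower, 0 adjusted over the list alone; adjusted p = 0.0177; adjusted p = 0.613 with an estimated correlation). Both calls were lost without any of 4 arrays, C57Bl/6J IC replicates 1 and 3 and MRL/MpJ IC replicates 1 and 3 (adjusted p 0.0776 to 0.194 for the receptors and 0.0671 to 0.374 for heat shock genes). Azurophil granule genes (1 of 14 higher and 1 lower; 3 higher and 1 lower adjusted over the list alone; adjusted p = 0.00390; adjusted p = 0.420 with an estimated correlation) and markers of eosinophils, basophils and mast cells (0 of 18 higher and 1 lower, Hdc at -0.66; 1 higher and 1 lower adjusted over the list alone; median 0.32; adjusted p = 0.00106; adjusted p = 0.272 with an estimated correlation) were called higher. Fcgr4 was at -1.13 ± 0.11, with the Fc receptor list not called (1 higher and 2 lower of 23; 1 higher and 3 lower adjusted over the list alone; camera, adjusted p = 0.504). The count of called genes fell to 719 without MRL/MpJ IC replicate 1 and to 492 when only the groups compared entered the model, and was 2762 with array quality weights.

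The strain differences at rest and with IC had a Pearson r of 0.758 and a Spearman correlation of 0.509 across genes. Of the genes called, 288 were higher and 312 lower in MRL/MpJ in both states, against 12.7 and 12 for independent lists, and 1 was called in opposite directions. Of 1529 genes called in either state, 94.7% differed with the same sign.

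The question named in the design, whether the strains respond differently to IC, was tested as the difference between the 2 responses. Pilrb1 rose with IC in C57Bl/6J, from 9.17 ± 0.44 to 11.27 ± 0.04, and was at 7.87 ± 0.15 and 7.78 ± 0.12 in resting and IC arrays of MRL/MpJ, a difference of -2.19 ± 0.23 (limma, adjusted p = 0.00474). Without detection calls, whether Pilrb1 lay above background in MRL/MpJ could not be judged, and strain variants under its probes were not tested. Egr3, an early growth response factor, fell in both strains and by more in MRL/MpJ, from 11.31 ± 0.05 to 9.25 ± 0.06 against 10.93 ± 0.19 to 10.33 ± 0.19, a difference of -1.46 ± 0.16 (limma, adjusted p = 0.00474). Aplnr rose by more in MRL/MpJ (difference 1.00 ± 0.12; limma, adjusted p = 0.00823), from 7.87 ± 0.01 to 9.33 ± 0.12, a call lost without MRL/MpJ resting replicate 1 (limma, adjusted p = 0.0501). The endosomal GTPase Rhob differed by 1.15 ± 0.15 (limma, adjusted p = 0.0182), at 11.16 ± 0.09 and 10.21 ± 0.21 in C57Bl/6J against 10.23 ± 0.10 and 10.44 ± 0.06 in MRL/MpJ. Nrros, a regulator of reactive oxygen species, differed by 0.90 ± 0.13 (limma, adjusted p = 0.0445), at 10.65 ± 0.09 and 10.63 ± 0.16 in C57Bl/6J against 9.34 ± 0.06 and 10.21 ± 0.03 in MRL/MpJ.

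These were the 5 genes of 22180 that passed, 3 with a positive and 2 with a negative difference, and 1020 genes had an unadjusted p under 0.05. The next smallest p-values belonged to Hspa4l (-0.83) and Ttc30b (1.28), each with adjusted p = 0.0511 (limma), and Tnfaip3 was at -1.03 ± 0.21 (adjusted p = 0.197). With the replicate number as a block within each strain, the adjusted p was 0.0519 for Rhob and 0.0560 for Nrros, and with all probe sets tested 0.0634 and 0.0963 (limma). Leaving out 1 array ended the call of Rhob in 6 of 12 fits (limma, adjusted p 0.0563 to 0.0900) and that of Nrros in 11 of 12 (0.0609 to 0.195).

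Camera called 3 lists in this comparison, all with a more negative response in MRL/MpJ. NF-kB target cytokines and chemokines had a median difference of -0.32 (adjusted p = 1.28e-09), NF-kB feedback and survival genes of -0.32 (adjusted p = 1.28e-09) and immediate early genes of -0.23 (adjusted p = 1.19e-09). With an estimated correlation their adjusted p was 0.286, 0.144 and 0.410, and with fry, which tests a list against no change rather than against other genes, 0.172, 0.0426 and 0.209. Adjusted over all genes, 0 of 25, 0 of 25 and 1 of 32 members passed, and 9 were lower in each list adjusted over the list alone. Single members include Tnf (-0.81 ± 0.16; limma, adjusted p = 0.197) and Tnfaip3, which were not called. The mean of the cytokine list was 9.80 ± 0.06 and 9.59 ± 0.23 in resting and IC arrays of C57Bl/6J, and 9.84 ± 0.06 and 9.14 ± 0.19 in those of MRL/MpJ. The other 23 lists were not called, with interferon-stimulated genes at an adjusted p of 0.465 and Fc receptor genes at 0.103. The count of 5 became 3 without C57Bl/6J resting replicate 2 or 3 or MRL/MpJ resting replicate 3 or IC replicate 3, and 2, Pilrb1 and Egr3, without MRL/MpJ resting replicate 1. It was 12 without the dimmer 50% of genes (3 positive and 9 negative), 15 with an intensity trend and robust variance (4 and 11), and 275 with array quality weights (76 and 199).

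**Figure D3:**
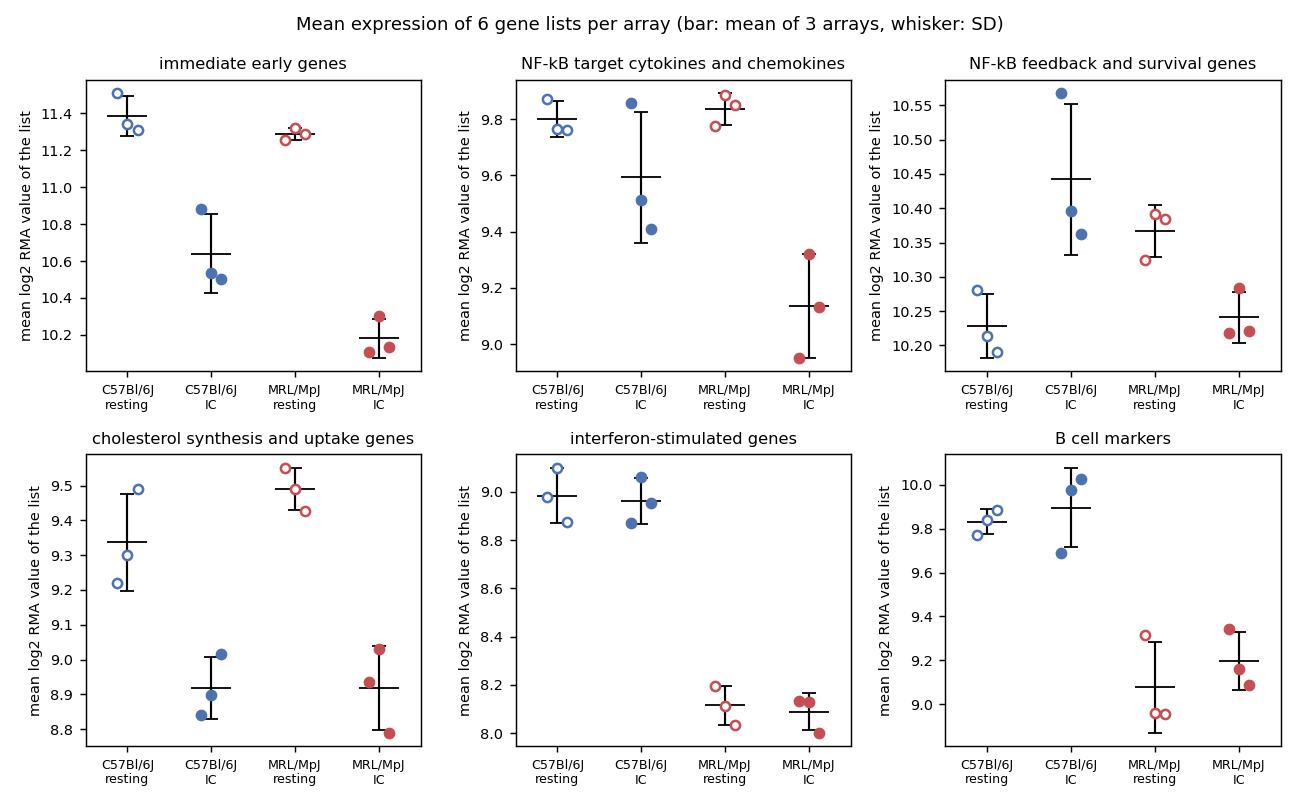
Mean log2 RMA value over the measured members of 6 gene lists in each array, by strain and state, with open circles for resting and filled circles for IC arrays, blue for C57Bl/6J and red for MRL/MpJ, the mean of 3 arrays as a bar and the SD as whiskers. Immediate early genes fall from 11.39 and 11.29 to 10.64 and 10.18, and interferon-stimulated genes lie near 8.98 in C57Bl/6J and 8.12 in MRL/MpJ at rest.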

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

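The estimated correlation was an alternative set before, but its use as a test of genes that vary together, and the test of array means, were chosen only after the result was seen, while the tests of C57Bl/6J IC replicate 2, of another normalization and of other splits of the samples were chosen before. In 5 genes and 3 gene lists the response to IC differed between the strains by a test of the difference itself. The 3 list calls were lost with an estimated correlation (camera, adjusted p = 0.286, 0.144 and 0.410). Pilrb1 differed by -2.19 and Egr3 by -1.46, and both calls held in every alternative fit. None of these fits could show whether Pilrb1 lay above background in MRL/MpJ. Aplnr differed by 1.00, Rhob by 1.15 and Nrros by 0.90 (log2). With the replicate number as a block within each strain, Rhob and Nrros were not called (limma, adjusted p = 0.0519 and 0.0560). Exchanging strain labels within each state gave 5 or more called genes in 4 of 100 splits, the real one included, and the highest other split called 275 genes. In that split 0 resting and 4 IC arrays were given the other strain, so that the strain difference itself entered the contrast. Because such splits mix in the strain difference and part arrays of the same number, they say nothing on whether chance gave the count of 5.

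The pattern weighed was the more negative response of MRL/MpJ in NF-kB target cytokines and chemokines (median difference -0.32), NF-kB feedback and survival genes (-0.32) and immediate early genes (-0.23). C57Bl/6J IC replicate 2, which stood apart in its median over all probe sets, was argued against as the cause. Without it 3 of the 3 lists were still called at the preset correlation. After cyclic loess normalization 3 of the 3 were also called at that correlation. That step started from the deposited RMA values, so it cannot decide whether the authors' own normalization gave the pattern. On these lists C57Bl/6J IC replicate 1 lay highest of its group (cytokines 9.86 against 9.51 and 9.41). Leaving out any 1 array ended 0 of the 3 calls at the preset correlation. That genes of a list vary together between arrays, which could produce such calls, stays open: with an estimated correlation 0 of the 3 lists passed, yet array means, in which such genes count once, differed for the feedback list (limma, adjusted p = 0.0238), though not for cytokines (0.118) or immediate early genes (0.184). With the replicate number as a block within each strain the array means of all 3 lists differed (limma, adjusted p = 0.000380, 0.000380 and 0.000440), a block that only the C57Bl/6J arrays bear out. A biological difference between the strains stays open too, as does any day or handling difference between the preparations, which was not tested.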

How the results depend on the processing

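The fit without both C57Bl/6J arrays numbered 2 was chosen only after the data were seen, and all other alternatives were set before. With 3 arrays per group and no detection calls, signal over background could not be judged gene by gene. Among genes named by the rule and called, 29 of 51 (IC in C57Bl/6J), 43 of 56 (IC in MRL/MpJ), 37 of 58 (strains at rest), 39 of 61 (strains with IC), 2 of 5 (interaction) and 56 of 66 (mean response) were called in every alternative but the stricter thresholds. None turned in direction. Of the lists called, 2 of 9, 2 of 7, 1 of 5, 0 of 10, 0 of 3 and 2 of 7 kept their call likewise, estimated correlation and fry included. The causes of the moves below were not tested, except where fewer genes or arrays entered by construction.

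Array quality weights (0.162 for C57Bl/6J IC replicate 2 to 6.02 for MRL/MpJ IC replicate 1) gave 1825, 5529, 3020, 2762, 275 and 5291 calls in these 6 comparisons. Requiring 2-fold change gave 67, 119, 171, 185 and 82 for all but the interaction, and an adjusted p under 0.01 gave 334, 556, 473, 565, 3 and 1140. With only the groups compared, the count was 246 for IC in C57Bl/6J, 1670 for the strains at rest and 492 for the strains with IC. Without both C57Bl/6J arrays numbered 2, IC in C57Bl/6J gave 397. The interaction count of 5 became 12 without the dimmer 50% of genes, 3 with all probe sets, and 15 with an intensity trend and robust variance.

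Leaving out each array gave 380 to 792 calls (IC in C57Bl/6J), 576 to 815 (IC in MRL/MpJ), 541 to 911 (strains at rest), 719 to 1071 (strains with IC), 2 to 7 (interaction) and 1379 to 2341 (mean response). The correlation of the IC responses ran from 0.578 to 0.652, that of the strain differences from 0.688 to 0.759. Without the dimmer 50% of genes the former was 0.742, and over called genes alone the correlations were 0.863 and 0.912. The median of erythroid markers with IC in C57Bl/6J ran from -0.0917 to 0.325 when 1 array was left out. The direction of their test turned from down to up without resting replicate 1, where the median was 0.325 and the list passed (camera, adjusted p = 0.0461).

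With the replicate block within each strain, IC in C57Bl/6J gave 827 calls, IC in MRL/MpJ 1245, the interaction 6 and the mean response 2235. With a replicate block shared by all groups, the 6 counts were 656, 1031, 924, 1010, 3 and 1905. In C57Bl/6J the block within the strain ended the calls of Casp4, Eomes and Hdc (limma, adjusted p = 0.0656, 0.0603 and 0.0713) and brought in Stfa1 and Tfrc (0.0464 and 0.0124). It changed no other call there among named genes or lists. In MRL/MpJ the deviations of same-numbered arrays were correlated at 0.24, 0.02 and 0.33, and all but replicate 2 matched their own number best. Across the strains they were correlated at 0.23, 0.03 and 0.04 at rest and at -0.02, -0.43 and -0.39 with IC.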

Other observations

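In this part the tests of the state labels, of other marrow cells, of B cells and of variants under the probes were chosen only after the result was seen, and the bound for neighbouring genes was tightened, and their 2-fold set chosen, after a first result. Genes outside the lists called by camera also moved with IC when both strains were averaged. The glucose and hypoxia genes went both ways, with the growth factor Vegfa at -0.75 ± 0.10 and the prolyl hydroxylase Egln3 at 0.62 ± 0.13 (3 rose and 5 fell of 24; 5 rose and 5 fell adjusted over the list alone; camera, adjusted p = 0.417). Of inflammasome and cell death genes (4 rose and 2 fell of 22; 6 rose and 2 fell adjusted over the list alone; camera, adjusted p = 0.488), the death receptor Fas (0.77 ± 0.06; limma, adjusted p = 4.19e-06) and Nlrp12 (0.73 ± 0.07) rose, and Pmaip1, which encodes the BH3-only protein Noxa, fell by 0.83 ± 0.14. Of adhesion and surface activation genes (7 rose and 5 fell of 21; 10 rose and 6 fell adjusted over the list alone; camera, adjusted p = 0.417), Clec4n (0.78 ± 0.10) rose, while Cd69 (-0.55 ± 0.07) and Cd274, which encodes PD-L1 (-0.56 ± 0.10), fell. The group means of Clec4n and Cd274 moved unequally in the strains, but neither gene was called in the test of the difference between the 2 responses. Clec4n went from 8.68 to 9.96 in C57Bl/6J and from 9.33 to 9.61 in MRL/MpJ, and Cd274 from 9.57 to 9.40 and from 9.66 to 8.72. The redox gene Srxn1 was at -0.82 ± 0.12 and the granzyme gene Gzmb at -1.14 ± 0.12 (limma, adjusted p = 2.71e-05).

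At rest, genes called between the strains stood next to each other on the GRCm38.p6 assembly in several places, chosen here after their values were seen. The interleukin receptor genes Il1r1, Il1rl2, Il18r1 and Il18rap were all higher in MRL/MpJ, by 0.46, 0.83, 0.56 and 0.44. Rnf144a, Rsad2 and Cmpk2 were lower (-1.16, -1.50 and -0.74), as were Apobec3 and Cbx7 (-1.91 and -0.65) and, in the MHC, H2-Ob, H2-Ab1, H2-Aa and H2-Eb1 (-0.69, -0.93, -0.81 and -0.71). The B lineage and plasmacytoid factor Spib (-1.37 ± 0.23) and the lymphoid marker Ly6d (-1.02 ± 0.17) were lower, and the NF-kB inhibitor Tnip3 was higher (1.25 ± 0.20; limma, adjusted p = 0.00256). Of 10869 probe sets with no gene or several, 256 differed between the strains at rest, 70 higher and 186 lower in MRL/MpJ.

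The hypothesis tested on these neighbours was linked strain variation, since stretches of the genome of different descent would carry several differing genes side by side. Of genes called at rest, 16.2% had a called neighbour, against a mean of 8.86% and at most 13% in 1000 random draws (permutation p = 0.001). The same number of genes with the smallest p for IC reached 16.0%. Among the 171 genes that differed at least 2-fold, the share was 12.3% (permutation p = 0.001), against at most 9.36% in random draws. For as many IC genes, picked by the smallest p and not by size of change, it was 3.51% (permutation p = 0.1). Linked variation and shared regulation of neighbours cannot be told apart over all called genes, because there the IC genes clustered as much. The 2-fold strain genes exceeded the draws and the 171 IC genes did not, but the 2 sets were picked by different rules. Their shares can therefore not be set against each other, and shared regulation of such genes was not tested.

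Immediate early genes are known to rise within minutes of a stimulus, yet arrays labelled IC had less of them, with a median of -0.86 over both strains. A wrong label on some arrays was argued against, since in 6 of 6 IC-labelled arrays the mean of the list lay below every resting array of the strain. A different share of monocytes or B cells was argued against, since the lowest median among 7 marker lists was 0.0258 (monocyte markers, SD of members 0.175). The erythroid, T and NK cell, dendritic cell and megakaryocyte lists averaged only 7.49 to 7.87 in resting C57Bl/6J. Their markers had little room to fall, so for these cells the test cannot decide. Dividing marrow cells were not among the 7 lists, and proliferation genes were called lower with IC, so a different share of them stays open. State labels reversed throughout cannot be told apart from a true fall, because the median of -0.86 would turn its sign with the labels, as would every other IC contrast. Induction of these genes during isolation of the resting cells may also account for it and was not tested.

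Interferon-stimulated genes were lower in MRL/MpJ, and so were B cell markers. Fewer B cells in the MRL/MpJ preparations stay open as the cause. Of the list, 2 genes, Oas2 (-2.21 ± 0.13) and Oasl2, fell by over 2 SE more than Cd22, the B cell marker that fell most (-1.48), too few against the 3 set as the bound, and genes picked for passing exclude nothing. Strain variants spread evenly under the probes of the array were argued against, since 61.5% of list members were called lower, against 1.93% of 19935 other genes (Fisher's exact p = 2.22e-21). Variants under the probes of these genes alone, a lower interferon tone in MRL/MpJ and inherited differences in single genes stay open as untested.

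For the 4 comparisons of 3 arrays with 3, the real split was 1 of 10, too few for a share under 0.05. It called 736 genes for IC in C57Bl/6J (highest other split 31), 1109 for IC in MRL/MpJ, 1007 for the strains at rest and 1123 for the strains with IC (highest other split 0 in each of these 3). In C57Bl/6J, 4 splits, the real one included, parted all 3 pairs of same-numbered arrays, and the others of these called 0 genes, while splits that parted fewer pairs called up to 31. For the mean response, 1 of 100 splits, the real one, called as many as 2003 genes, and the highest other called 187. Of these splits, 40 parted all 3 C57Bl/6J pairs, and among them 1, the real one, called as many, with 7 genes in the highest other. This argues against chance without excluding it, and the pairs were taken from the data alone.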
